A study of Rattus norvegicus with 4 samples.

How the data were processed

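Total RNA of rat samples labelled brain, adrenal medulla was measured on 4 arrays, 1 each for undigested and digested samples at day 1 and day 7. The deposited values were linear signal intensity per probe set, with 1322 probe sets of which 59 were controls. The mean after trimming 2% of the values at each end was 2516 on 3 of the arrays and 2515 on the digested day 7 array, so the arrays appear to have been scaled to a common mean; how the authors computed the signals and scaled them is not given in the sources used here. Precision is limited by the number of arrays, 1 per group. Gene names came from the probe table and were looked up by gene identifier in a current RefSeq gene table, which held 1132 of the identifiers and changed 0 symbols. Of the 1263 probe sets other than controls, 1137 named 1 gene (720 different genes), 8 named several and 118 named none.

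Each array was scaled to a common median over the probe sets other than controls, with factors of 0.925, 1.01, 1.09 and 0.984 for undigested and digested day 1 and undigested and digested day 7. Scaled values were floored at the 20th percentile of all values (a signal of 51.8) and taken to log2. Probe sets with a mean log2 value at or above the median of all (a signal of 229) were analysed, which left 632 probe sets of 386 genes, and differences with a value at the floor were not ranked. With 1 array per group the main comparisons had no test: a probe set was counted when its log2 difference was at least 1 either way, that is, at least 2-fold. The differences between digested and undigested at day 1 and at day 7 share no array, and neither do the day differences in undigested and digested samples, so probe sets past 2-fold in the same direction in both were counted beside the number expected if the pairs were unrelated. Pearson and Spearman correlations were taken across probe sets, with 95% intervals from 1000 bootstrap draws of probe sets, which leave out the spread between samples. For 125 genes with several analysed probe sets (305 in all), the pooled SD of the log2 difference between probe sets of a gene was 0.32 for digestion at day 1, 0.52 at day 7, 0.52 for the day difference in undigested samples and 0.41 in digested samples.

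For 24 gene lists of cell types, signalling and stress, the median over a list's genes was taken for each comparison, with a gene's value the mean over its analysed probe sets. It was ranked among 10000 random lists of the same size matched on mean log2 signal in 10 bins, and lists with fewer than 3 analysed genes got no median. Named genes followed a rule. For digestion and for the day, it took up to 12 genes each way that passed 2-fold in both pairs of arrays, ranked by the smaller of the paired differences, or filled to 8 with the next genes of the same direction in both. This gave 1 gene past 2-fold and 7 filled for higher with digestion, 0 and 8 for lower, 2 and 6 for higher at day 7 and 4 and 4 for lower. It also took the 5 largest differences of differences each way, up to 4 genes per list with the largest smaller difference, and Th, Dbh, Pnmt, Ddc, Chga, Chgb, Penk and Npy. Where a gene had several analysed probe sets, the brightest was named.

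The alternatives tried were the values as deposited, quantile normalisation, a floor at the 40th percentile, an offset in place of the floor, no filter on dim probe sets, the 316 brightest probe sets alone, thresholds of 1.5-fold and 3-fold, 1 value per gene and an additive fit of digestion and day on 1 residual degree of freedom with limma 3.58.1 in R 4.3.3. The residual of the additive fit is the change of the digestion difference between the days. Its error also borrows a spread pooled over the probe sets of these arrays. With 1 array per group, this error mixes the spread between samples with any true change of the digestion difference between the days. No spread between replicates was measured apart from it, and whatever the samples of a day share is left out. Cyclic loess was added after the data were seen. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data made from these arrays, with 50 probe sets shifted at both days at each fold. The simulated noise was normal and independent between probe sets. All folds were shifted in the same run, which makes the adjusted p of the additive fit more lenient. Its recovery need not hold where few probe sets differ. The 2-fold rule at both days recovered 10 of the 50 at 2-fold, 39 at 3-fold, 46 at 4-fold and 50 at 8-fold, and called 3 of 432 unshifted probe sets; the additive fit recovered 18, 43, 46 and 50 and called 6. Of 200 simulated lists of 18 unshifted probe sets 10 fell outside the middle 95% of random lists (5.0%). When shifted by a log2 of 0.4, 130 of 200 did (65.0%). The first share follows from drawing both kinds of list at random from independent values. It does not show how lists of genes that vary together behave.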

Results

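Total RNA from rat samples labelled brain, adrenal medulla was measured on 4 single-channel oligonucleotide arrays. The samples were labelled undigested or digested and came from day 1 or day 7 of a time course, so each of the 4 groups held 1 array. What was digested is not stated in the labels, and no purpose of the study is given in the sources used here. With 1 array per group, no difference could be set against a spread between replicates, and the main comparisons are reported as sizes without a test; an additive limma fit stands beside those that use all 4 arrays. The median signal of the 1263 probe sets other than controls was 284 on the undigested day 1 array, 260 on the digested day 1 array, 242 on the undigested day 7 array and 267 on the digested day 7 array. Th, the gene of tyrosine hydroxylase, the rate-limiting enzyme of catecholamine synthesis, had scaled signals of 221633, 233350, 256725 and 163625 on the same arrays. The analysed set held 632 probe sets of 386 named genes and further probe sets without a gene name. Over it, the median log2 difference was 0.12 for digested minus undigested at day 1, -0.05 for the same at day 7, 0.17 for day 7 minus day 1 in the undigested samples and 0.04 in the digested samples. Values as deposited moved these medians by -0.13, 0.14, -0.23 and 0.04, quantile normalisation by -0.13, 0.03, -0.17 and -0.01, and cyclic loess by -0.14, 0.03, -0.19 and -0.02. The files gave no genome build and no positions for the probe sets. No signal was shown to be above background, and differences that rest on a signal under 104, which is 2 times the floor of 51.8 and a limit chosen after the values were seen, are imprecise in size. Of the genes named below, these are Cacnb1 (64.1) on the undigested day 1 array and Gsta1 (78.2) and Bdkrb1 (84.7) on the digested day 1 array. On the undigested day 7 array they are Nr4a3 (65.2), Tgfbr1 (93.3), Cspg5 (96.8), Gap43 (102) and Tgfbr3 (103.7), and on the digested day 7 array Npy (58.2), Cx3cl1 (74.6) and Htr1d (85.5).

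The control probe sets set both day 7 arrays apart from the day 1 arrays. Bacterial transcripts that are added at hybridisation, read by 9 probe sets, were 2.55-fold lower on the digested day 7 array than on the other 3 arrays (median log2 -1.35). The same median was 0.33 for the undigested day 1 array, 0.36 for the digested day 1 array and 0.57 for the undigested day 7 array. Control transcripts carrying a poly-A tail, read by 12 probe sets, had a median of 0.37 on the digested day 7 array. The signal ratio of the 3′ to the 5′ probe set of beta-actin, a sign of how complete the labelled RNA is, was 1.42 and 1.48 on the undigested and digested day 1 arrays. It was 2.66 on the undigested day 7 array and 1.35 on the digested day 7 array. The same ratio of GAPDH ran from 1.01 to 1.18 over the 4 arrays, and that of hexokinase from 1.05 to 1.40. Both were highest on the undigested day 7 array, as was that of beta-actin, but by a smaller margin. The next highest were 1.104 for GAPDH on the digested day 7 array and 1.31 for hexokinase on the undigested day 1 array.

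At day 1 the digested and undigested samples differed in few transcripts. Cacnb1, which codes for a beta subunit of voltage-gated calcium channels, was 6.80-fold higher in the digested sample (log2 2.77). Bdkrb1, the gene of the bradykinin B1 receptor, was 4.70-fold lower (log2 -2.23). The lower signals of the pair, 64.1 for Cacnb1 in the undigested and 84.7 for Bdkrb1 in the digested sample, lay near the floor of 51.8, so the folds are imprecise. Cspg5, a chondroitin sulphate proteoglycan of the nervous system, was 2.42-fold higher, the potassium channel gene Kcnh4 2.40-fold, the inducible nitric oxide synthase gene Nos2 2.13-fold, the serotonin transporter gene Slc6a4 2.09-fold and the growth factor gene Fgf2 2.03-fold. Lower signals in the digested sample were also read for the sodium channel gene Scn4a (log2 -1.46), the alpha-1D adrenergic receptor gene Adra1d (log2 -1.38) and the acid-sensing channel gene Asic1 (log2 -1.18). Dbh, which codes for the enzyme that turns dopamine into noradrenaline, was 1.44-fold higher in the digested sample, and Th stood at a log2 difference of 0.07, which turned negative in the values as deposited. Of the 632 analysed probe sets, 22 (3.48%) differed at least 2-fold, 13 of them higher and 9 lower in the digested sample. The split was 7 higher and 12 lower in the values as deposited, 11 and 12 after quantile normalisation and 10 and 12 after cyclic loess. All 22 lay in the dimmer part of the analysed set, and 0 of the 316 brightest probe sets passed 2-fold. The SD of the log2 difference over probe sets was 0.43, and the 2 arrays correlated with r = 0.981 across probe sets, which are not independent replicates.

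At day 7 more transcripts differed between the digested and undigested samples. Nr4a3, which codes for an orphan nuclear receptor induced by cell activity, had a log2 difference of 3.46, higher in the digested sample. Tgfbr1, the gene of the type I receptor of TGF-beta, was 5.82-fold higher by its brighter probe set, and its other analysed probe set gave a log2 difference of 0.82. Cspg5 was 5.27-fold higher, the plasma membrane calcium pump gene Atp2b1 3.81-fold, the retinoic acid receptor gene Rarb 3.75-fold and the TGF-beta co-receptor gene Tgfbr3 3.68-fold. Npy, which codes for neuropeptide Y, was 6.45-fold lower in the digested sample (log2 -2.69), and the chemokine gene Cx3cl1 was 4.24-fold lower. Htr1d, a serotonin receptor gene, had a log2 difference of -2.07, and the GABA transporter gene Slc32a1 one of 1.62. The catecholamine genes Th and Dbh were 1.57-fold and 1.41-fold lower in the digested sample. Of the 632 analysed probe sets, 72 (11.4%) differed at least 2-fold, 44 higher and 28 lower in the digested sample, and the split was 53 higher and 20 lower in the values as deposited. The SD over probe sets was 0.69, which is 1.61 times that at day 1 (95% bootstrap interval over probe sets 1.38 to 1.88), and r between the arrays was 0.955. Among the 316 brightest probe sets 12 passed 2-fold. These differences rest on the digested array with low hybridisation controls and the undigested array with the beta-actin ratio of 2.66. Those of Npy, Cx3cl1 and Htr1d rest on signals of 58.2, 74.6 and 85.5 in the digested sample, near the floor of 51.8. Those of Nr4a3, Tgfbr1, Cspg5 and Tgfbr3 rest on signals of 65.2, 93.3, 96.8 and 103.7 in the undigested sample, so these 7 folds are imprecise.

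In the analysed set, few genes differed in the same way between digested and undigested samples at both days. Cspg5 passed 2-fold at both, 2.42-fold and 5.27-fold higher in the digested samples, and it was the only one of the 632 probe sets to do so, against 1.30 expected if the days were unrelated. Without the filter on dim probe sets, 44 of 1263 passed in the same direction at both days, 24 higher and 20 lower, against 22.5 expected, and 37 passed in opposite directions. Over these 1263 probe sets the day 1 and day 7 differences had r = -0.003, and 45.2% had the same sign. A floor at the 40th percentile gave 2 in the same direction. Pde4c, a gene of a cyclic AMP phosphodiesterase, was 1.91-fold and 3.12-fold higher, and Arrb1, which codes for an arrestin that uncouples receptors from G proteins, 1.73-fold and 3.16-fold. Both probe sets of Clns1a, a gene involved in chloride current and splicing, read higher in the digested samples at both days, 1.53-fold and 1.64-fold by the brighter one. Slc6a11, a GABA transporter gene, was 1.87-fold and 1.42-fold higher. Lower in the digested samples at both days were Cntn2, a cell adhesion gene of axons, by 1.82-fold and 2.27-fold, the neurotrophin gene Ntf3 by 1.63-fold and 2.23-fold, the interleukin 6 receptor gene Il6r by 1.46-fold and 2.20-fold and the chloride transporter gene Clcn4 by 1.52-fold and 2.14-fold. Nes, the gene of the progenitor cell filament nestin, was 1.36-fold and 1.47-fold lower, and the log2 differences of Grip2 were -0.43 and -0.97 and of Syt8 -0.39 and -0.64. In opposite directions, 3 probe sets passed 2-fold at both days, those of Cacnb1 (log2 2.77 and -1.20), Nos2 (log2 1.09 and -1.48) and 1 of the 2 of Nr4a1 (log2 1.07 and -1.44), all higher in the digested sample at day 1 and lower at day 7, while the other probe set of Nr4a1 was higher at both (log2 0.94 and 0.49). The correlation of the day 1 and day 7 differences across probe sets was r = 0.02 (95% bootstrap interval -0.06 to 0.11) with a Spearman rho of 0.02, and 46.0% of the probe sets had the same sign. With limma's additive fit, no probe set had an adjusted p under 0.05 for digestion, 42 had an unadjusted p under 0.05 against 31.6 expected, and the lowest adjusted p was 0.439.

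**Figure D1:**
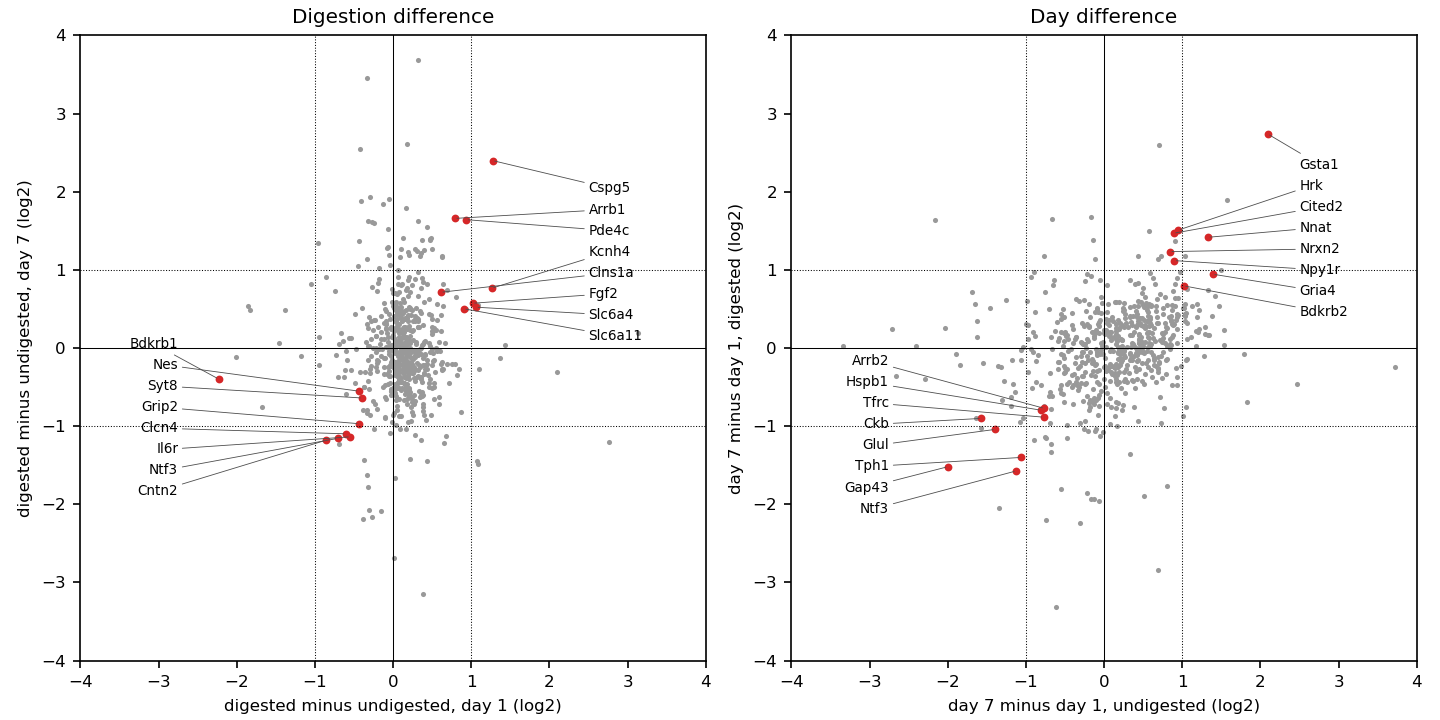
Log2 differences of the 632 analysed probe sets, with 1 point per probe set. The left panel sets digested minus undigested at day 7 against the same at day 1 (r = 0.02), and the right panel sets day 7 minus day 1 in the digested samples against the same in the undigested samples (r = 0.28); labelled points are named genes such as Cspg5, higher in the digested samples at both days, and Gsta1 and Gap43, higher and lower at day 7 in both.

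Among named genes, each by its brightest probe set and with no value at the floor, the digestion difference at day 7 minus that at day 1 was greatest upwards for Nr4a3, at a log2 of 3.80, followed by Tgfbr1 at 2.96, Tgfbr3 at 2.29, Atp2b1 at 2.22 and Rarb at 1.97. The other analysed probe set of Tgfbr1 gave digestion differences of only 0.64 at day 1 and 0.82 at day 7. Each of these 5 genes was lower on the undigested day 7 array than on the undigested day 1 array, by 4.46-fold for Nr4a3, 6.56-fold for Tgfbr1, 4.10-fold for Tgfbr3, 3.15-fold for Atp2b1 and 3.08-fold for Rarb, while the other probe set of Tgfbr1 had a log2 of -0.51. Downwards it was greatest for Cacnb1 at -3.97, followed by Npy at -2.70, Nos2 at -2.57, Cx3cl1 at -1.92 and the muscarinic receptor gene Chrm1 at -1.89. Between day 1 and day 7, Npy was 9.91-fold lower in the digested samples and 1.53-fold lower in the undigested samples, and Cx3cl1 was 4.71-fold and 1.24-fold lower, with digested day 7 signals of 58.2 and 74.6 near the floor. Cacnb1 was higher at day 7 in the undigested samples, from a signal of 64.1 near the floor of 51.8 to 844, and 1.19-fold lower in the digested samples. With Nr4a3 at 65.2, Tgfbr1 at 93.3 and Tgfbr3 at 103.7 on the undigested day 7 array, the sizes for these 6 genes and the order of the genes are imprecise. The difference of differences passed 2-fold for 91 probe sets, 44 upwards and 47 downwards, with 67 and 27 in the values as deposited, 55 and 36 after quantile normalisation and 56 and 36 after cyclic loess. It uses all 4 arrays and leaves no residual, so no test was possible.

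In the undigested samples, more transcripts passed 2-fold between the days than in the digested samples, a difference that was not tested. Gap43, which codes for a protein of growing axons, was 4.0-fold lower at day 7, to a signal of 102 near the floor, Ckb, the brain-type creatine kinase gene, 2.97-fold and Glul, the gene of glutamine synthetase, 2.62-fold. Gsta1, a glutathione S-transferase gene, was 4.27-fold higher, although its probe set is of a kind that can detect related members of the family. Dbh was 2.44-fold higher at day 7, Penk, which codes for the precursor of the enkephalins, 2.08-fold and Ddc, the gene of aromatic amino acid decarboxylase, 1.93-fold by its brighter probe set. The interleukin 6 receptor gene Il6r was 2.51-fold higher and the AMPA receptor gene Gria4 2.62-fold. Of the 632 probe sets, 84 (13.3%) differed at least 2-fold, 46 higher and 38 lower at day 7. The split turned to 20 higher and 59 lower in the values as deposited, 29 and 52 after quantile normalisation and 25 and 53 after cyclic loess, and the SD over probe sets was 0.72. The undigested day 7 array had a beta-actin 3′ to 5′ ratio of 2.66 against 1.42 at day 1.

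In the digested samples, Gsta1 was 6.68-fold higher at day 7 than at day 1, from a signal of 78.2 near the floor, Hrk, a gene that promotes cell death, 2.85-fold by its brightest probe set, Cited2, a gene of a transcription co-regulator, 2.77-fold and Nnat, which codes for the membrane protein neuronatin, 2.67-fold. Npy was 9.91-fold lower and Cx3cl1 4.71-fold, both imprecise for day 7 signals of 58.2 and 74.6, Nos2 3.40-fold, Ntf3 2.97-fold and Gap43 2.86-fold. Bdkrb1, with a signal of 84.7 in the digested sample at day 1, was 3.18-fold higher at day 7, and Nr4a3 was 3.12-fold higher. Th was 1.43-fold lower at day 7, Dbh 1.20-fold higher and Penk 1.69-fold higher. Of the 632 probe sets, 51 (8.07%) differed at least 2-fold, 21 higher and 30 lower at day 7, with an SD over probe sets of 0.61. Among the 316 brightest, 11 passed 2-fold in the digested samples and 30 in the undigested samples.

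Several genes differed between the days in the same direction in both digestion states. In all, 11 probe sets passed 2-fold in the undigested and the digested samples, 5 higher and 6 lower at day 7, against 3.33 expected if the pairs were unrelated. The split was 4 and 6 in the values as deposited and 3 and 8 after quantile normalisation and after cyclic loess. Higher at day 7 were Gsta1 (4.27-fold undigested, 6.68-fold digested), Nnat (2.52-fold and 2.67-fold), 1 probe set of Hrk (2.96-fold and 3.73-fold) and a pair of probe sets without a gene name. Lower were Gap43 (4.0-fold and 2.86-fold), Ntf3 (2.18-fold and 2.97-fold), Tph1, the gene of an enzyme of serotonin synthesis (2.09-fold and 2.64-fold), a pair of probe sets of Glul, of which the brighter was 2.62-fold and 2.06-fold lower, and 1 probe set without a gene name. Short of 2-fold in 1 of the states, Gria4 was 2.62-fold and 1.93-fold higher at day 7, the neuropeptide Y receptor gene Npy1r 1.86-fold and 2.17-fold, Cited2 1.85-fold and 2.77-fold, Nrxn2, a gene of synaptic adhesion, 1.79-fold and 2.35-fold and the bradykinin B2 receptor gene Bdkrb2 2.03-fold and 1.74-fold. Ckb was 2.97-fold and 1.87-fold lower by its brighter probe set, the small heat shock protein gene Hspb1 1.75-fold and 1.74-fold by its brightest probe set and the transferrin receptor gene Tfrc 1.71-fold and 1.85-fold. In opposite directions only Nr4a3 passed 2-fold, with log2 differences of -2.16 undigested and 1.64 digested. The correlation of both day differences across probe sets was r = 0.28 (95% bootstrap interval 0.19 to 0.36) with a Spearman rho of 0.33, and 61.6% of the probe sets had the same sign. Over all 1263 probe sets, without the filter, r was 0.090, with 46 in the same direction against 27.2 expected and 39 in opposite directions. Pairing each day 7 array with the day 1 array of the other digestion state gave r = 0.26 and 9 probe sets in the same direction. The error of limma's additive fit holds the difference of differences and a spread pooled over probe sets. The difference of differences mixes the spread between samples with any true change of the digestion difference between the days. Whatever the samples of a day share is left out of the p-values of the fit. With limma's additive fit on 1 residual degree of freedom, only Gsta1 had an adjusted p under 0.05 for the day (log2 2.42, SE 0.324, adjusted p = 0.0283, higher at day 7 in both states), a value that includes the digested day 1 signal of 78.2 near the floor, while Gap43 had a log2 of -1.76 and an adjusted p of 0.0811. An unadjusted p under 0.05 was found for 91 probe sets.

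**Figure D2:**
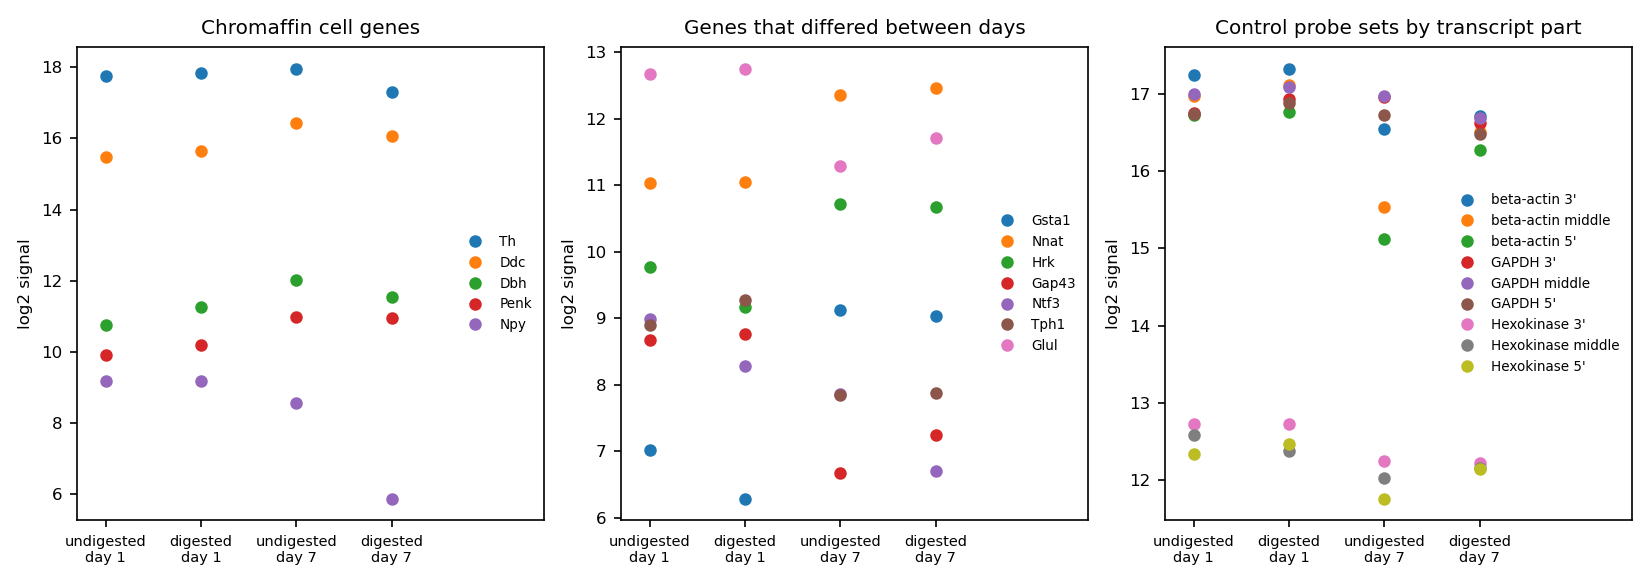
Log2 signal on each of the 4 arrays after median scaling, with 1 point per probe set and array. The panels show the chromaffin cell genes Th, Ddc, Dbh, Penk and Npy, with Npy 6.45-fold lower in the digested than in the undigested day 7 sample, the genes that differed between the days in both digestion states, and the 3′, middle and 5′ control probe sets of beta-actin, GAPDH and hexokinase, with a beta-actin 3′ to 5′ signal ratio of 2.66 on the undigested day 7 array.

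Gene lists for cell types, signalling and stress had been fixed before the data were examined, and 16 of the 24 had at least 3 analysed genes. A list's median log2 difference was ranked among 10000 random lists matched on mean signal, and the percentile describes these arrays and is not a p-value. Genes with several probe sets entered as the mean. In the digestion difference at day 7 the probe sets had opposite signs within genes such as Nr4a1, Hmox1, Mag, Maoa, Scarb1, Tubb5, Bdnf and Hspb1. Medians outside the middle 95% were found for 0 of the 16 lists in the digestion difference at day 1 and 3 in that at day 7. They were found for 1 in the day difference of the undigested samples and 2 in that of the digested samples. Each count stands against 0.8 expected for lists drawn at random, whose genes need not vary together.

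Genes of chromaffin cells, the catecholamine cells of the adrenal medulla, were lower in the digested than in the undigested sample at day 7. Their median log2 difference was -0.57 over the 6 analysed genes (percentile 0.815), with Npy 6.45-fold lower, to a signal of 58.2 near the floor, Ddc 1.73-fold as the mean of its probe sets, Th 1.57-fold and Dbh 1.41-fold. Maoa, which codes for an enzyme that breaks down monoamines, was at -0.19 and Penk at -0.03, of which Penk was higher in the values as deposited. Quantile normalisation, which by construction leaves no difference in Th, the highest signal on each array, brought the median to -0.32 (percentile 6.46), and without the filter on dim probe sets it was -0.19 over 11 genes (percentile 24.6). At day 1 the median was 0.18 (percentile 86.1), between the days 0.63 in the undigested samples (percentile 97.48, inside the middle 95%) and -0.17 in the digested samples (percentile 13.7), the last turning to 0.12 after quantile normalisation. Penk and Npy also stand in the list of opioid and pain peptides. The names Pnmt, Chga and Chgb were not carried by any probe set of this array. On the digested day 7 array, which all of these lower values share, the hybridisation controls were 2.55-fold lower than on the other arrays, and the undigested day 7 array had the beta-actin ratio of 2.66.

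By their median, genes of neuron structure were lower on the digested day 7 array than on either array it was compared with. Which cells carried these transcripts was not measured, so a change in neurons cannot be read from them. Between digested and undigested samples at day 7, 14 of the 18 analysed genes were lower and 4 higher, with a median log2 difference of -0.34 (percentile 2.12). With each scaling 13 or 14 were lower, and the median was -0.19 in the values as deposited (same percentile), -0.35 after quantile normalisation and -0.31 after cyclic loess. Microtubule and filament genes were among them, with Map2 at -0.44 and Nefh at -0.36, together with the adhesion gene Ncam1 at -0.33, while Map1b stood at 0.84. Nefm, the gene of the medium neurofilament chain, at -0.87 and Mapt, the gene of tau, at -0.74 were chosen after their values were seen. Between day 7 and day 1 in the digested samples, 14 of the 18 were lower, with a median of -0.28 (percentile 0.25), and the percentile stayed under 2.5 in all 7 alternative settings. Examples were Gap43 at -1.52 and Snap25, a gene of the vesicle fusion machinery, at -0.76, while the vesicle gene Rab3a was at 1.14. Gap43 and Snap25 were also lower at day 7 in the undigested samples, at -1.999 and -0.799, so their fall was not particular to the digested samples. Against the undigested day 7 sample, the 4 higher genes were Map1b, Rab3a at 0.593, Gap43 at 0.575 and Snap25 at 0.202. In the undigested samples the median between the days was 0.42 (percentile 85.7). At day 1, 17 of the 18 were higher in the digested sample by a median of 0.15 (percentile 79.9), but 10 in the values as deposited, 9 after quantile normalisation and 11 after cyclic loess. Single genes of other lists were also lower in the digested sample at day 7, such as the oligodendrocyte gene Cnp at -0.65, the matrix genes Plat at -0.36 and Bcan at -0.33 and B2m at -0.62, and the hybridisation controls were low on that array. The percentile at day 7 was 3.73 without the filter on dim probe sets and 5.01 in the 316 brightest.

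Of the lists of cell activity, stress and survival, only cell death and survival lay outside the middle 95% of random lists in the digested against the undigested sample at day 7. The cell death and survival list had a median of 0.49 over 7 genes (percentile 97.7), but of 0.08 in the 316 brightest probe sets (5 genes, percentile 53.6) and 0.14 without the filter on dim probe sets (12 genes, percentile 88.2). This comparison rests on the array with low hybridisation controls and that with the beta-actin ratio of 2.66. In the list 5 genes were higher and 2 lower. Higher were Bcl2l2 at 1.29, Bcl2l1 at 0.53 and the inhibitor of apoptosis gene Birc2 at 0.51. So were the caspase gene Casp2 at 0.49 and Bad at 0.08. Lower were the death receptor gene Tnfrsf1a at -0.27 and Bax at -0.13, which turned positive with another scaling. The list's median between the days was 0.37 in the digested samples (percentile 91.5), where all 7 genes were higher but 6 after quantile normalisation. The survival genes Bcl2l1 and Bcl2l2 stood at 0.78 and 0.46 there, and in the undigested samples Bcl2l2 stood at -0.89 and the list's median at 0.29 (percentile 55.7). The immediate early genes had a median of 0.35 over 9 genes at day 7 (percentile 95.9, and 87.2 after quantile normalisation), with Nr4a3 at 3.46 and Junb at 0.35 but Nr4a1 at -0.47, the mean of 2 probe sets at -1.44 and 0.49. In the undigested samples their median between the days was -0.37 (percentile 2.32), with Jun at -1.31 and Nr4a3 at -2.16 but Nr4a1 at 1.14, on the array with the beta-actin ratio of 2.66, and the digested samples had 0.11 (percentile 64.0). The stress and heat shock list had a median of 0.27 over 9 genes at day 7 (percentile 97.4, inside the middle 95%, and 87.8 after quantile normalisation). In it 6 genes were higher, such as the superoxide dismutase genes Sod2 at 1.02 and Sod1 at 0.74, and 3 lower, which were the chaperone genes Hsp90ab1 and Hspd1 at -0.44 each and Hmox1 at -0.15, of which Hsp90ab1 and Hmox1 turned positive with other scalings. Its medians between the days were 0.42 in the undigested (percentile 71.2) and 0.07 in the digested samples (percentile 48.2), with the metallothionein gene Mt2A at 0.73 and 1.17 and Hspb1 at -1.06 and -0.72 as the mean of its probe sets. At day 1 the medians of the 3 lists were 0.06, 0.07 and 0.14 (percentiles 12.6, 57.0 and 72.3), and each turned negative with quantile normalisation. The median of the cell death list at day 7 lay outside the middle 95% in 3 of 7 alternative settings, and so did that of the immediate early genes between the days in the undigested samples, which ran from -0.61 to -0.12.

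Growth factor genes went both ways. The neurotrophin gene Ntf3 was lower in the digested sample at both days (log2 -0.71 and -1.16), Igf2, an insulin-like growth factor gene, was at -0.59 and 1.33, and Fgf2 was at 1.02 and 0.57. The list's medians over 11 genes were -0.03 at day 1 (percentile 27.2) and -0.02 at day 7 (percentile 56.0) for digestion, and 0.15 and -0.03 between the days in the undigested and digested samples (percentiles 67.6 and 48.9); those at day 7 and between the days changed sign in the values as deposited. Among growth factor receptors Igf1r was at 0.43 and 1.55 and the insulin receptor gene Insr at -0.25 and -1.03. The medians of the 8 receptors were 0.13 and -0.14 for digestion (percentiles 71.0 and 41.1), the latter 0.01 in the values as deposited, and -0.23 and -0.11 between the days (percentiles 4.98 and 27.9). The macrophage and leukocyte list, with 4 analysed genes including Nos2 and the chemokine receptor gene Cxcr4, had medians of 0.19 and -0.20 for digestion (percentiles 68.0 and 22.5). Between the days it had 0.13, negative with each other scaling, and -0.18 (percentiles 45.9 and 19.9).

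Of the 8 ionotropic glutamate receptor genes, 7 were higher at day 7 than at day 1 in the digested samples, with a median of 0.34 (percentile 97.8), Gria4 at 0.94 and Gria2 at 0.54, and the median stayed outside the middle 95% in 4 of 6 alternative settings. Without the filter on dim probe sets it fell to 0.04 over 16 genes (percentile 59.8), and it rests on the digested day 7 array, where the hybridisation controls were 2.55-fold lower. In the undigested samples their median was 0.14 (percentile 60.5), which turned negative in the values as deposited, with Gria4 at 1.39. Their digestion medians were -0.21 at day 1 (percentile 3.41) and 0.01 at day 7 (percentile 66.2), with the NMDA receptor genes Grin1 at 0.64 and 1.02 and Grin2a at -0.37 and -0.50. Calcium channel genes had digestion medians of 0.27 and -0.50 over 7 genes (percentiles 95.03 and 2.53), with Cacnb1 at 2.77 and -1.20, Cacna2d1 at 0.46 and -0.50 and Cacna1g at 0.46 and 0.63. Between the days they had 0.49 in the undigested and -0.02 in the digested samples (percentiles 86.8 and 32.4), the latter 0.02 in the values as deposited. Sodium channel genes had digestion medians of -0.49 and 0.14 over 5 genes (percentiles 11.2 and 56.2) and day medians of -0.14 and 0.60 (percentiles 63.2 and 94.5). The 12 potassium channel genes had 0.23 and -0.21 for digestion (percentiles 84.7 and 30.9) and 0.32 and 0.02 between the days (percentiles 84.0 and 59.5), with Kcna5 at 0.67 and -1.12 and Kcnma1 at -0.58 and 1.03 for digestion. GABA and glycine genes, 7 in all, had 0.10 and 0.34 for digestion (percentiles 57.5 and 83.0), the former negative with each other scaling, and -0.21 and -0.13 between the days (percentiles 24.3 and 33.4), the latter 0.15 after quantile normalisation.

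Acetylcholine signalling genes had digestion medians of 0.14 and -0.03 over 10 genes (percentiles 60.9 and 59.4), turning to -0.02 with cyclic loess and 0.11 in the values as deposited, and day medians of -0.02 and -0.17 (percentiles 15.4 and 15.4). Among them the nicotinic receptor gene Chrnb2 was at 0.37 and 0.89 and Chrm1 at 0.44 and -1.45 for digestion. The 8 monoamine receptor and transporter genes had 0.02 and 0.25 for digestion (percentiles 58.9 and 81.7), the former negative with each other scaling, and -0.21 and -0.22 between the days (percentiles 26.1 and 17.8), with Htr2a at 0.38 and 0.85 and Htr1d at -0.30 and, down to a signal near the floor, -2.07 for digestion. Genes of the opioid and pain peptide list, which also holds receptor genes, had -0.05 and -0.34 over 10 genes for digestion (percentiles 14.7 and 7.24). Between the days they had -0.02 and 0.06 (percentiles 40.5 and 57.4), of which -0.02 turned to 0.02 after quantile normalisation. The mean of both digestion differences put their median at -0.33 (percentile 0.62), the only 1 of the 16 lists outside the middle 95% by that mean, against 0.8 expected. In this list 5 genes, all of receptors, were lower at both days, 1 was higher and 4 went opposite ways. The bradykinin receptor genes were lower, Bdkrb1 at -2.23, to a signal of 84.7 near the floor, and -0.40, and Bdkrb2 at -0.30 and -0.53. So were the somatostatin receptor gene Sstr4 at -0.33 and -0.42 and the tachykinin receptor gene Tacr3 at -0.54 and -0.28. The receptor gene Npy1r was at 0.15 and 0.37, of which 0.15 turned negative with other scalings. The peptide genes Penk (0.27 and -0.03), Pnoc (0.51 and -0.18) and Npy (0.01 and -2.69) went opposite ways. Of these, -0.03 and 0.01 changed sign with other scalings.

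**Figure D3:**
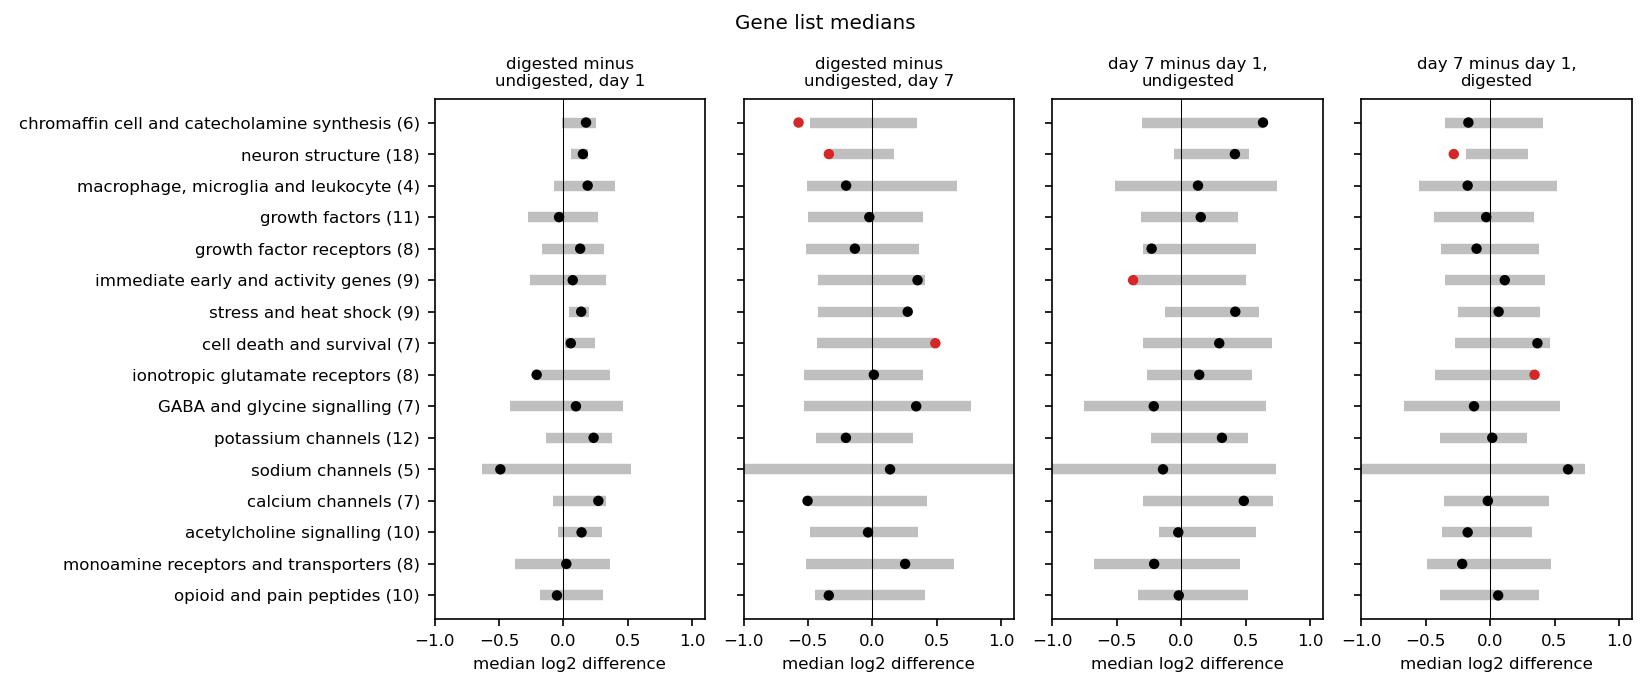
Median log2 difference of each of the 16 gene lists in the 4 comparisons, with the middle 95% of 10000 matched random lists in grey and medians outside it in red. Chromaffin cell and neuron structure genes lie below that range in digested minus undigested at day 7, at -0.57 and -0.34, and neuron structure genes also between the days in the digested samples, at -0.28.

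Markers of the other cell types were read by too few analysed probe sets for a median. The astrocyte genes were Glul, at 0.20 and 0.64 for digestion at day 1 and day 7 and -1.29 and -0.86 between the days in the undigested and digested samples, and the glutamate transporter gene Slc1a3, at -0.62, -0.29, -0.11 and 0.23. The oligodendrocyte genes were Cnp, at 0.18, -0.65, 0.73 and -0.11, and Mag, at -0.03, -0.34, 0.08 and -0.23, of which 0.08 turned negative with other scalings. From the list of vessels and matrix, Bcan was at -0.11, -0.33, 0.50 and 0.28 and Plat at 0.30, -0.36, -0.07 and -0.74. The adrenal cortex list was left with Scarb1, a lipoprotein receptor gene, at 0.34, -0.04, -0.07 and -0.44, of which -0.04 turned positive with other scalings. Grm4 of the metabotropic glutamate receptors was at 0.01, 0.52, 0.05 and 0.56, of which 0.01 and 0.05 turned negative with other scalings. Of the housekeeping list, Tubb5 was at 0.30, 0.09, -0.52 and -0.74 and B2m at 0.24, -0.62, 0.64 and -0.22. The red blood cell and cell cycle lists had 0 genes on the array.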

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

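The tests of the undigested day 7 array alone and those with cyclic loess scaling were chosen only after the results were seen.

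Nr4a3 stood out because its day difference went opposite ways, with a log2 of -2.16 in undigested samples and 1.64 in digested samples. Cacnb1 and Nos2 stood out because their digestion differences went opposite ways at the separate days, at 2.77 and -1.20 for Cacnb1 and 1.09 and -1.48 for Nos2. With 1 array per group, the difference between these effects was not tested for any of the 3 genes. Among the control probe sets, which no comparison used, the hybridisation controls stood at a median log2 of -1.35 on the digested day 7 array against the other arrays. The 3′ to 5′ signal ratio of beta-actin was 2.66 on the undigested day 7 array.

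The digestion difference was wider at day 7 than at day 1, with SDs over probe sets of 0.69 and 0.43 and a ratio of 1.61 (95% bootstrap interval 1.38 to 1.88). Intensity-dependent scaling as the whole cause was argued against by a ratio of 1.60 (1.36 to 1.88) after cyclic loess, and noise of dim probe sets by a ratio of 2.75 (2.42 to 3.10) in the 316 brightest probe sets. The undigested day 7 array alone, whose own variance was 3.27 (2.33 to 4.63) times that of a day 1 array, cannot be told apart from a wider difference. The same ratio for the digested day 7 array was 1.94 (1.22 to 2.93), and its interval comes too near 1 to decide. An effect of digestion that differs between the days stays open and was not tested against the spread of samples.

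Chromaffin cell and neuron structure genes, pooled, were lower in the digested day 7 sample. Their median log2 difference to the undigested sample was -0.35 over 24 genes, 20 of them lower (percentile 0.6 of matched random lists). The pool joined the 2 of the 16 lists that lay below the middle 95% in this same comparison. Its percentile and its count of lower genes therefore add no support to those of the single lists. For the pool, intensity-dependent scaling as the whole cause was argued against by a median of -0.31 after cyclic loess. This lay outside the -0.22 to 0.19 of the middle 95% of random lists, although the pool was selected in this same comparison. Of its 24 genes 18 are neuron genes, so this speaks for that list rather than for the chromaffin genes. For the chromaffin genes alone intensity-dependent scaling was not argued against, since quantile normalisation put their median inside the middle 95%. That scaling leaves no difference in Th by construction. To look for a high value on the undigested day 7 array alone, each day 7 array was set against the mean of the day 1 arrays. For the 18 neuron genes the median was -0.12 on the digested day 7 array, below the -0.09 to 0.36 of random lists. On the undigested day 7 array it was 0.25, inside -0.11 to 0.47. A fall of these genes between the days would also give a low digested value, so the test cannot decide. For the 6 chromaffin genes a high undigested value cannot be told apart from a low digested value. Their median was -0.051 on the digested day 7 array, inside -0.29 to 0.46, and 0.55 on the undigested one, inside -0.36 to 0.58. A biological effect of digestion at day 7 and a fault of either day 7 array stay open for both lists. For the chromaffin genes intensity-dependent scaling also stays open, and these causes were not tested against each other.

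The day differences went the same way in both digestion states, with r = 0.28 (0.19 to 0.36) across probe sets and 11 probe sets past 2-fold in the same direction against 3.33 expected. Intensity-dependent scaling as the whole cause was argued against by r = 0.28 (0.19 to 0.36) after cyclic loess, and noise of dim probe sets by r = 0.52 (0.44 to 0.60) in the 316 brightest probe sets, while r was 0.090 over all 1263 probe sets without the filter. Whether the arrays of a day were processed together is not given in the labels. The hybridisation controls moved by a median log2 of 0.18 (range -0.14 to 0.66) between the days in undigested samples and -1.32 in digested samples, which bears on the hybridisation step only. A shared earlier step therefore cannot be told apart from the effect of the days, which also stays open.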

How the results depend on the processing

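Cyclic loess and its values were chosen after the data were seen; the other alternatives were planned. Of the values of counts and correlations 53 kept their size and 35 did not. The balance of higher and lower turned for digestion at day 1, from 13 and 9 to 7 and 12 in the values as deposited, for the day in undigested samples, from 46 and 38 to 20 and 59, and for the difference of differences, from 44 and 47 to 67 and 27. All 3 also turned at 3-fold, to 3 and 5, 5 and 15, and 22 and 17, and with quantile normalisation and cyclic loess. Digestion at day 7 turned from 44 and 28 to 86 and 90 at 1.5-fold, and the day in both states from 5 and 6 to 6 and 5 with a floor at the 40th percentile, among other settings. The causes of the moves were not tested, except that a lower or higher threshold and a smaller or larger set of probe sets change a count by construction. Counts are given in the order digestion at day 1, digestion at day 7, day in undigested, day in digested, digestion at both days, day in both states and difference of differences. No filter on dim probe sets (1263) gave 208, 273, 284, 242, 44, 46 and 366, with r = 0.090 between the day differences. The 316 brightest probe sets gave 0, 12, 30, 11, 0, 2 and 20, with r = 0.52. A threshold of 1.5-fold gave 73, 176, 235, 150, 16, 58 and 233, and one of 3-fold 8, 25, 20, 18, 0, 1 and 39. A floor at the 40th percentile gave 2 for digestion at both days and r = 0.33 between the day differences, and the offset gave 7 for the day in both states. The additive limma fit gave 0 for digestion and 1 for the day. Of the list medians 71 moved and 345 did not, of the named genes' values 37 and 863, and of the list genes' values 35 and 2885. Leaving out the undigested or the digested day 7 array, both doubted for their controls, removes the comparisons that use it: the digestion difference at day 1 (22 probe sets) needs neither, the day difference in digested samples (51) does not need the first and that in undigested samples (84) does not need the second. Signal over background limits the dimmer probe sets: of those past 2-fold, 22, 60, 54 and 40 lay in the dimmer part of the analysed set in the first 4 comparisons. The labels pair no samples of 1 animal or culture, and the additive fit compares digestion within each day.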

Other observations

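The genes in this part were chosen after their values were seen, among those read by several analysed probe sets. All 4 probe sets of Snap25, a gene of synaptic vesicle fusion, were lower at day 7 than at day 1, by log2 differences of -1.04 to -0.68 in undigested samples and -0.90 to -0.61 in digested samples. The vesicle gene Syn2 was lower by all 3 of its probe sets, at -0.68 to -0.12 and -1.33 to -0.70, and so was the microtubule gene Map1b, at -1.06 to -0.33 and -0.54 to -0.15. All 3 probe sets of the glutamine synthetase gene Glul were lower at day 7, at -1.58 to -0.92 and -1.04 to -0.51, and so were all 3 of Hspb1, at -1.19 to -0.81 and -0.80 to -0.63, and both of Ckb, at -1.57 to -1.14 and -0.90 to -0.56. Higher at day 7 were all 3 probe sets of the cell death gene Hrk, at 0.95 to 1.57 and 0.66 to 1.90, both of the haem oxygenase gene Hmox1, at 0.72 to 1.04 and 0.41 to 0.69, and both of Clns1a, at 0.44 to 0.97 and 0.54 to 0.97. The 3 probe sets of Bdnf, a neurotrophin gene, went both ways, at -0.67 to 0.93 in undigested samples and -0.61 to 0.90 in digested samples.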
